A study of Sus scrofa with 12 samples.

How the data were processed

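Gene expression was measured on 12 two-colour Agilent arrays in pools of Day 9 pig embryos. Per the labels' protocols, embryos of 3 FE and 3 SE sows were sexed by PCR, 5 male and 5 female embryos of each sow were pooled separately, and RNA was amplified and labelled with Cy3 and Cy5. The deposited table holds 1 log ratio per probe and array, made by the authors, with both signs and array medians within 0.0108 of 0. The deposited values were read as log2 ratios from their range of -4.99 to 5.97, since neither the log base nor the normalization was stated. Scanning, background correction, normalization and the numerator channel are not given in the sources used here, and single-channel intensities were not analysed here.

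Of 43794 probes, 25 with a missing value on at least 1 array were left out, which leaves 43769. Gene symbols came from the platform's gene table, with 345 symbols brought up to date from the pig RefSeq table. They name 18110 of the probes and leave 25659 unnamed.

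The labels give FE with Cy3 and SE with Cy5 on all 12 arrays, although the second array of each set is described as a dye swap. The relative direction was taken from the values in a check that uses no FE/SE outcome: the deviations of the first arrays from their mean were correlated, over sets and probes, with those of the swap arrays from theirs. The correlation was -0.728, so the signs of the swap arrays were turned. The 2 arrays of a set were then averaged, which made each of the 6 sets 1 replicate.

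The set ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per sex, prior degrees of freedom 2.3). Contrasts were the mean of both sexes against 0, each sex against 0, and the male minus the female ratio. Benjamini-Hochberg adjustment was over all probes at a threshold of 0.05, and confidence intervals were at 95%. Differences between sets were tested with limma's moderated F on the 12 arrays with a term for array role. Gene lists were tested on gene means with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Adjustment was over the 23 lists. Shares of probes on lists were compared with Fisher's exact test, two-sided. Male and female embryos were never on the same array, so their levels were not compared.

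The lists held 612 genes, 429 of them measured: markers of the trophectoderm, epiblast, hypoblast, gastrulation, uterus and blood, and genes of steroid synthesis and conceptus signalling, the insulin-like growth factor system, imprinting, DNA methylation and chromatin, X inactivation and the Y chromosome, the cell cycle, apoptosis, oxidative stress and heat shock, the unfolded protein response, glycolysis, oxidative phosphorylation, cholesterol synthesis, nutrient transport, retinoid signalling, the interferon response, ribosomal proteins and housekeeping. The lists, the tests, the threshold, the rule for naming genes and most alternatives were chosen before the data were examined. The rule named, for each contrast, the genes of largest change among those past the threshold with 1 sign in all sets, or, where fewer than 10 passed, the 10 genes of smallest p. It also named the 3 members of each list with the smallest p for both sexes, the 15 genes with the largest F between sets and the 2 members of each list with the largest F. The probe of smallest p stands for its gene.

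The comparison of FE and SE embryos of both sexes was tested on simulated data with the spread of these sets. It recovered 36% of 50 probes changed by 0.5 in log2 units, 86% of 50 changed by 1, and 100% of 50 changed by 2 and of 50 changed by 4, with 8 unchanged probes called. The test of lists found the 1 shifted list and called 0 others, and the test between sets called 0 probes under technical noise alone. The simulated sets were drawn independently, while real sets shared sows and had r of up to 0.50 (male set 2 with female set 2). The changed probes were also drawn at random from all probes, whose median SD between sets was 0.19. Real probes with a large ratio could spread far more, as NMU did with a ratio of -2.15 and an SD of 1.40. Of the 68 real probes with 1 sign in all 6 sets and a mean over 2-fold, 0 passed. Recovery and false calls in the real data may therefore differ, and the shares recovered do not carry over to such probes.

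Alternatives were single arrays or 1 array per set, the opposite relative direction, centred and scaled arrays, named probes alone, gene means, robust eBayes, array weights, the slide or the set number as a block, a threshold on unadjusted p and fold, and each set left out in turn. Other splits were all sign patterns of the sets, and all splits of 3 against 3 sets for the difference between sexes.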

Results

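Gene expression was compared in Day 9 pig embryos from FE sows, which were inseminated at an oestrus during lactation, and from SE (skip-a-heat) sows, which were inseminated at the oestrus after it. Each group had 3 sows, and pools of 5 male or 5 female embryos from individual sows gave 12 pools of RNA. Male and female pools came from the same 3 sows per group, so that the sets described below are not fully independent. On each of 12 two-colour arrays an FE pool was set against an SE pool of the same sex. The arrays formed 6 biological sets, 3 male and 3 female, and each set had a first array and a dye-swap array. All 12 arrays had a value for 43769 probes, of which 18110 carried the symbol of 1 of 11905 genes. The values were log ratios of FE and SE embryos, with an SD over probes of 0.333 to 0.472 per array. Signal intensities were not analysed here, and the number of arrays limits the precision of every ratio.

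As deposited, the ratios of the first and the dye-swap array of a set were negatively correlated over probes, with Pearson's r between -0.149 in male set 1 and -0.766 in female set 3. The labels named the same dye for FE on all 12 arrays, which contradicts a dye swap. The signs of the dye-swap arrays were therefore turned, and the ratio of a set is the mean of its first array and its turned swap array. A positive ratio below has the sign of the first arrays. Because neither the numerator channel nor a settled dye for each group was given, which of the FE and SE embryos had the higher level is not stated.

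**Figure D1:**
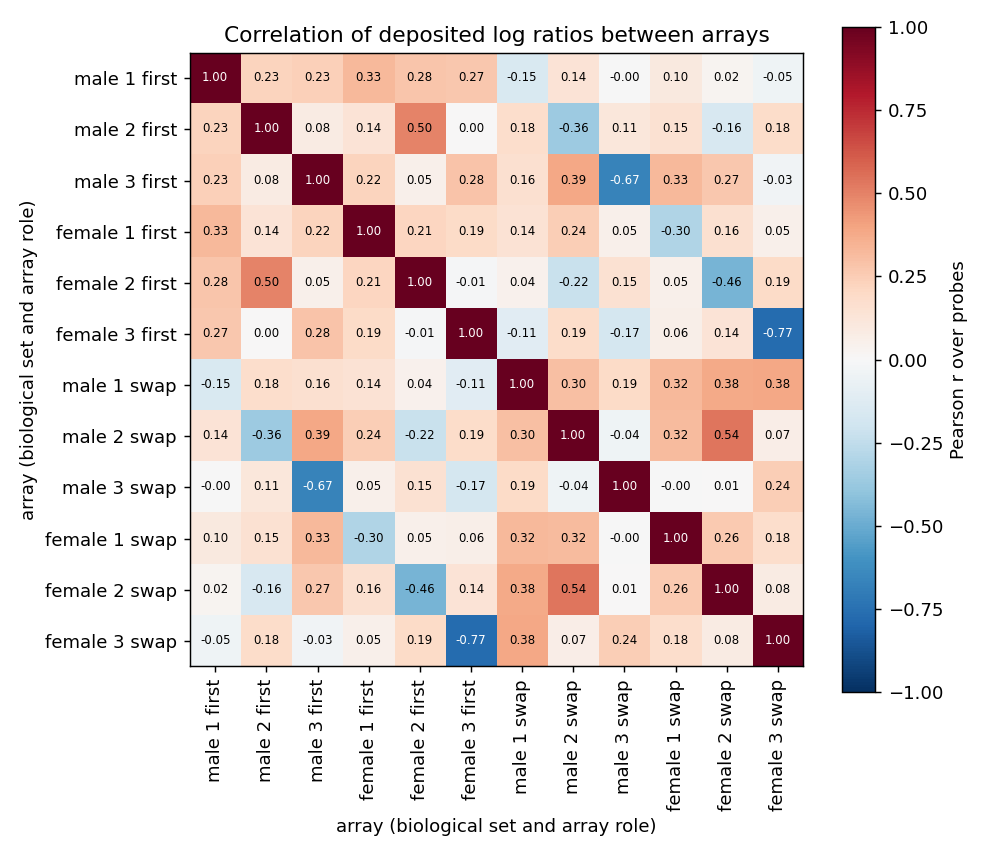
Pearson's r over 43769 probes between the deposited log ratios of the 12 arrays, with arrays on both axes named by biological set and array role. First arrays of different sets had a median r of 0.22 with each other, swap arrays 0.24, and the 2 arrays of a set were negatively correlated in all 6 sets (-0.15 to -0.77).

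The first comparison asked whether the mating strategy altered gene expression in the embryos of both sexes. MAN2C1, the gene of a mannosidase that trims free glycans in the cytosol, was the named gene that passed the test, with a ratio of 0.96 ± 0.10 (log2, SD, n = 6 sets; limma adjusted p = 0.0446) and a positive value in 6 of 6 sets. The second probe past the threshold, probe 1890, had no gene symbol and a ratio of 0.86 ± 0.07 (log2, SD, n = 6 sets; limma adjusted p = 0.0446), also positive in 6 of 6 sets. GSTM3, the gene of a glutathione transferase, followed with a ratio of -1.30 ± 0.34 and did not pass (limma adjusted p = 0.176). These were 2 of 43769 probes, while 2593 had an unadjusted p under 0.05 where 2188 would be expected by chance. The MAN2C1 call was not general to the gene: its other 6 probes had a median ratio of 0.07 and a highest of 0.46, and the mean over its probes was 0.27 (limma adjusted p = 0.937). Both calls ended when any 1 of the 6 sets was left out, with adjusted p between 0.12 and 0.74, and with the slide as a fixed block, with adjusted p = 0.189. The ratios themselves stayed at 0.93 to 1.00 for MAN2C1 and 0.84 to 0.89 for probe 1890 in these fits. Both calls also ended with the set number as a random block across the sexes, whose pools came from the same sows.

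Of the 10 named genes with the smallest p, the 9 besides MAN2C1 did not pass. AGR2, which codes for a disulfide isomerase of secretory epithelia, had a ratio of -0.48 ± 0.11 (SD, n = 6 sets), negative in 6 of 6. TMEM38B, the gene of a cation channel of the endoplasmic reticulum, had -0.65 ± 0.20. TCOF1, which serves the transcription of ribosomal RNA, had a ratio of 0.67 ± 0.47, and its second probe had 0.63. The T-cell adaptor gene LAT had 0.36 ± 0.17 and the chromatin gene SETD5 0.62 ± 0.23, with their second probes at 0.28 and 0.53. PRRC1 had a ratio of 0.53 ± 0.17 and the tetraspanin gene TSPAN6 -0.44 ± 0.14. SUCLG2, of the citric acid cycle, had 0.81 ± 0.28, but its other 2 probes had a median of 0.08, and the second probe of GSTM3 had -0.09. The adjusted p of AGR2 was 0.375, and those of the remaining 7 genes lay between 0.438 and 0.503. With the 12 arrays as separate values and the set as a random block, although the 2 arrays of a set hold the same pools and are not replicates, 349 probes passed, and GSTM3, AGR2, TMEM38B, TCOF1, LAT, SUCLG2, SETD5, PRRC1 and TSPAN6 were among them.

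**Figure D2:**
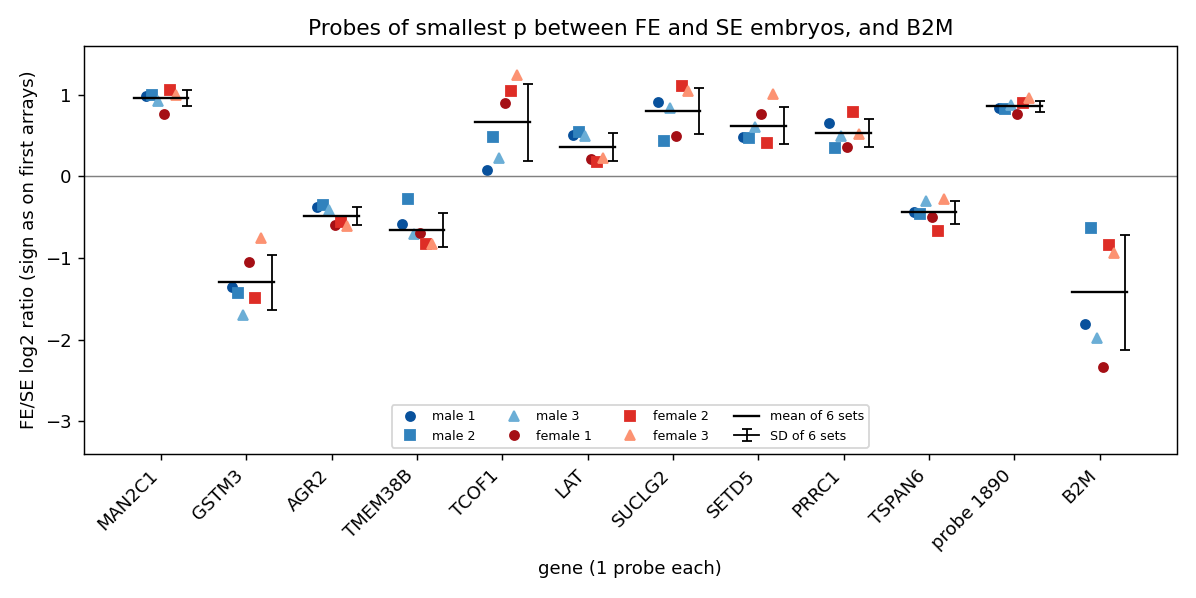
Log2 ratio of FE and SE embryos in each of the 6 biological sets (points, sign as on the first arrays) with the mean and SD of the 6 sets, for the 10 named genes of smallest p, for probe 1890 and for B2M. MAN2C1 lies between 0.77 and 1.06 in all sets, while B2M spans -2.34 to -0.63.

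B2M, which codes for the light chain of class I histocompatibility molecules and was on the list of housekeeping genes, had a ratio of -1.42 ± 0.71 (log2, SD, n = 6 sets) and was negative in 6 of 6 sets. It was the 1 probe of that list to pass when adjusted over the list alone (limma adjusted p = 0.0271), and it did not pass over all probes (limma adjusted p = 0.575). On the 23 lists fixed beforehand, 0 probes passed limma's test over all probes, and adjusted over the list alone 1 passed on the housekeeping list and 0 on each of the other 22. An unadjusted p under 0.05, which 5.92% of all probes had, was found for 10 of 47 probes of oxidative phosphorylation, 6 of 27 of cholesterol synthesis, 5 of 48 of DNA methylation and chromatin, 4 of 27 of nutrient transport, 4 of 64 of ribosomal proteins and 0 to 3 on each of the other 18 lists. Among developmental markers of smallest p, GATA3 of the trophectoderm had a ratio of 0.66 ± 0.78 and TEAD4 0.28 ± 0.21, SOX2 of the epiblast 0.16 ± 0.12, APOC3 of the hypoblast 0.55 ± 0.44, and BMP2 of the early mesoderm 0.39 ± 0.42. The conceptus cytokine gene IFNG had -1.74 ± 1.76, the apoptosis gene DIABLO -0.68 ± 0.49, the chaperone gene CANX -0.37 ± 0.15, and the retinoid-binding gene CRABP2 0.65 ± 0.51. COX6C of the respiratory chain had 0.66 ± 0.36 and RPS24 of the ribosome 0.91 ± 0.77. Averaged over its probes, no gene lay above 0.62 on the oxidative phosphorylation list or above 0.67 on the ribosomal list. The means of COX6C and RPS24 over their probes were thus smaller than the ratios of the probes given. None of these 11 genes passed over all probes. With the 12 arrays as separate values, which are not 12 replicates, B2M, DIABLO, CANX, CRABP2, COX6C and RPS24 did.

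The interval of limma's estimate was used to describe how precisely the mean ratio of each single probe was measured. The fit takes the sets as independent, although they shared sows. All probes are counted, since no filter on dim probes was run, and whether signal above background set the shares was not analysed. The shares therefore do not bound how far FE and SE embryos can have differed. For 97.4% of probes the 95% confidence interval of the mean ratio of both sexes lay within a 2-fold difference, and for 86.2% within 1.5-fold. The share within 2-fold was lower with means over the sexes as replicates, as given below. In male embryos the shares were 92.7% and 76.5%, and in female embryos 92.0% and 75.1%. Of all probes, 86 had a mean ratio over 2-fold, 70 of them positive and 16 negative.

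Whether genes of a shared function moved together between FE and SE embryos was tested on the 23 lists. Genes of cholesterol synthesis had a mean ratio of -0.22, with 11 of 12 genes negative and a negative list mean in 4 of 6 sets (camera adjusted p = 0.00311, and adjusted p = 0.815 with an estimated correlation). Genes of oxidative phosphorylation had a mean ratio of 0.08 and a median of 0.12, with 14 of 22 genes positive and a positive list mean in 4 of 6 sets (camera adjusted p = 0.0246, and adjusted p = 0.815 with an estimated correlation). FDPS, MSMO1 and HSD17B7, which encode enzymes of the cholesterol pathway, had ratios of -0.59, -0.28 and -0.24, each negative in 6 of 6 sets. On first arrays alone HSD17B7 had 0.075, and without male set 3 FDPS had -0.35. In oxidative phosphorylation COX6C and NDUFA1 were positive in 6 of 6 sets and UQCRB (0.48) in 5 of 6. The cholesterol call ended without male set 3 (-0.14, adjusted p = 0.0664) and without female set 3 (-0.15, adjusted p = 0.0711), and the oxidative phosphorylation call without male set 2 (0.01, adjusted p = 0.296), without female set 2 (0.03, adjusted p = 0.248) and with the slide as a fixed block (0.08, adjusted p = 0.0865). On first arrays alone neither list passed (cholesterol synthesis -0.20, adjusted p = 0.0702, and oxidative phosphorylation 0.10, 0.15), nor on swap arrays alone (-0.24, 0.0921, and 0.06, 0.387), while the means kept their sign. By slide, the mean of the cholesterol genes was 0.04 in male sets 1 and 2, -0.18 in female sets 1 and 2 and -0.52 in male and female set 3, and that of the oxidative phosphorylation genes was 0.07, 0.29 and -0.11.

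The other 21 lists did not pass, with adjusted p of 0.172 or more. The mean ratio was 0.02 for trophectoderm markers, -0.0013 for epiblast markers, 0.07 for hypoblast markers, 0.04 for gastrulation markers and -0.19 for the genes of steroid synthesis and conceptus signalling. Insulin-like growth factor genes had a mean of 0.0015, imprinted genes -0.04, DNA methylation and chromatin genes -0.03, X inactivation and Y-linked genes -0.02, and retinoid signalling genes -0.004. It was 0.02 for the cell cycle, -0.10 for apoptosis, 0.03 for oxidative stress and heat shock, -0.11 for the unfolded protein response and 0.05 for glycolysis. Genes of amino acid and nutrient transport had -0.03, the interferon response 0.03, ribosomal proteins 0.02, and housekeeping genes -0.05. Uterine markers had a mean of 0.0024 and blood markers 0.03. In 4 of the 23 lists, those of the epiblast, gastrulation, X and Y, and housekeeping genes, the mean and the median differed in sign.

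In male embryos the comparison asked whether the strategy acted in 1 sex alone. MAN2C1 (0.97 ± 0.04, SD, n = 3 sets) and GSTM3 (-1.49 ± 0.18) again had the smallest p and did not pass (limma adjusted p = 0.379 and 0.609). LAT had a ratio of 0.52 ± 0.03, the methionine synthase reductase gene MTRR 0.36 ± 0.09, and the polyadenylation gene CPSF1 0.60 ± 0.04. Negative ratios were found for the proteasome genes PSMD4 (-0.49 ± 0.20) and PSMC1 (-0.51 ± 0.06) and for MAPT (-0.64 ± 0.33), which codes for the tau protein, as well as for AGR2 (-0.38 ± 0.03) and TMEM38B (-0.52 ± 0.22). The second probe of MAPT had -0.04 and the other 5 of MTRR a median of 0.05. In male embryos limma found 0 probes past the threshold and 1418 with an unadjusted p under 0.05, fewer than the 2188 expected by chance. Of the 1418, 275 also had a ratio of at least 1.5-fold. On the 23 lists adjusted over the list alone, 0 probes passed.

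In female embryos TCOF1 had a ratio of 1.07 ± 0.17 (log2, SD, n = 3 sets; limma adjusted p = 0.674), and its second probe had 1.14. MAN2C1 (0.94 ± 0.15, limma adjusted p = 0.408), AGR2 (-0.59 ± 0.03), TMEM38B (-0.78 ± 0.08), GSTM3 (-1.10 ± 0.37) and SETD5 (0.73 ± 0.30) were also among the 10 of smallest p. ATP5G3, the gene of an ATP synthase subunit, had 0.56 ± 0.13, but -0.32 on the swap arrays alone. The elongation factor gene TCEA1 had -0.80 ± 0.23, and the galactosyltransferase gene B4GALT1 had -0.51 ± 0.06, with its second probe at 0.14. TALDO1, of the pentose phosphate pathway, had a ratio of 0.63 ± 0.16 and passed when adjusted over the list alone (glycolysis and glucose transport, limma adjusted p = 0.0188), as did the glutamate transporter gene SLC1A1 on the list of nutrient transport (-0.81 ± 0.19, limma adjusted p = 0.0413). Over all probes both had a limma adjusted p of 0.97. Averaged over its probes, no gene lay above 0.51 on the glycolysis list or below -0.41 on the nutrient transport list in female embryos. The means of TALDO1 and SLC1A1 over their probes were thus smaller in size than those of the probes given. In female embryos limma found 0 probes past the threshold and 2107 with an unadjusted p under 0.05, fewer than the 2188 expected by chance. Of the 2107, 571 also had a ratio of at least 1.5-fold. With the 12 arrays as separate values, which are not replicates within a set, 158 probes passed in female embryos, TCOF1, MAN2C1, AGR2, TMEM38B, GSTM3, TCEA1, TALDO1 and SETD5 among them, and 5 passed in male embryos, MAN2C1 and GSTM3 among them.

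The difference between the sexes in their ratio was tested in the same fit. PA2G4, which codes for a growth-regulating binding protein of ribosomal RNA, had a ratio of -0.45 in male and 0.56 in female embryos, and ATP5G3 of -0.16 and 0.56, with 3 sets of each sex. The same opposite signs were found for the phosphate carrier gene SLC25A3 (-0.29 and 0.41), RPL30 of the ribosome (-0.23 and 0.52), NDRG3 (-0.29 and 0.47), the poly(A)-binding gene PABPN1 (-0.29 and 0.54), the deadenylase gene PAN3 (-0.35 and 0.37), the polarity gene LIN7C (-0.67 and 0.25) and, the other way, ZMYND12 (0.27 and -0.29). TCOF1 was positive in both sexes (0.27 and 1.07). None of the 10 genes passed: limma found 0 probes past the threshold, and the smallest adjusted p was 0.9997. An unadjusted p under 0.05 was found for 819 probes, fewer than the 2188 expected by chance. Of the 819, 244 had a difference of at least 1.5-fold. The interval of the difference lay within 2-fold for 83.9% of probes.

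Among the lists, ribosomal protein genes had a mean ratio of -0.16 in male and 0.20 in female embryos, a difference of -0.36 that was negative for 26 of 34 genes (camera adjusted p = 8.69e-05, and adjusted p = 0.932 with an estimated correlation). Genes of oxidative phosphorylation had -0.06 in male and 0.22 in female embryos, a difference of -0.28 that was negative for 19 of 22 genes (camera adjusted p = 0.00069, and adjusted p = 0.932 with an estimated correlation). The ribosomal list mean was -0.05, 0.20 and -0.63 in the male sets and 0.17, 0.40 and 0.04 in the female sets. Slide 3 held male set 3 and female set 3, and there the difference was -0.67 for ribosomal proteins and -0.40 for oxidative phosphorylation. Between male sets 1 and 2 on slide 1 and female sets 1 and 2 on slide 2 it was -0.21 and -0.22. With the slide as a fixed block the difference comes from slide 3 alone, with 1 set per sex, and was again -0.67 and -0.40. Without female set 2 neither list passed (adjusted p = 0.0974 for ribosomal proteins and 0.177 for oxidative phosphorylation), and without male set 1 the oxidative phosphorylation call ended (adjusted p = 0.0596) at a similar difference of -0.27. Without male set 3 the differences were -0.13 and -0.15, and without male set 2 they were -0.54 and -0.42, and both lists passed in either case.

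**Figure D3:**
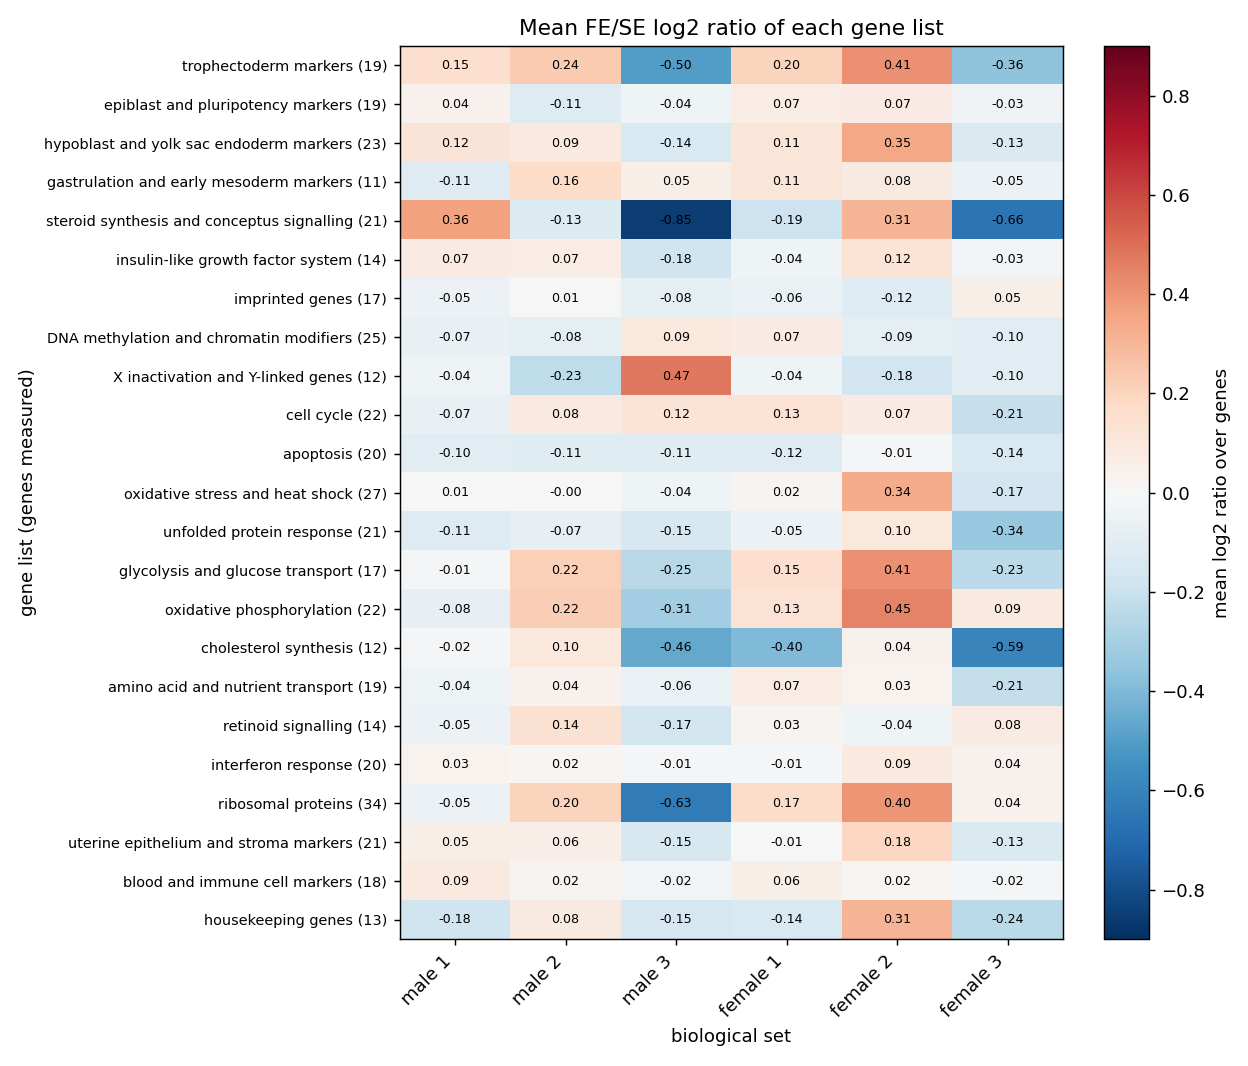
Mean log2 ratio of FE and SE embryos over the genes of each of the 23 lists (vertical axis, number of genes measured in brackets) in each of the 6 biological sets (horizontal axis, sign as on the first arrays). Trophectoderm markers were positive in 4 sets and negative in male set 3 (-0.50) and female set 3 (-0.36).

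The mean ratios of male and female embryos were correlated over probes with Pearson's r = 0.327 and Spearman's rho = 0.181. Probes are not independent replicates, and pools of both sexes came from the same sows, per the labels. Over the 32 patterns of signs of the 6 sets, 6 gave an r as large in size (exact permutation p = 0.188, two-sided), and the highest r of another pattern was 0.333.

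The ratios were also compared between the 6 sets, against the difference between the 2 arrays of a set. This compares the 6 sets and not the FE and SE groups. Both arrays of a set lay on 1 slide, so a difference between sets on different slides can come from pools or from slides. Slide 3 held male set 3 and female set 3. IL1B2, the interleukin gene that pig conceptuses express as they elongate, had a ratio of 2.58 in male set 1 and 2.64 in female set 2, but -2.51 in male set 3 and -2.18 in female set 3, each ± 0.16 (standard error, n = 2 arrays; limma adjusted p = 5.51e-08 over the 6 sets). IL1B had 3.95 in male set 1, 2.73 in female set 2 and -2.66 in male set 3 (± 0.20). IFNG, whose protein the elongating conceptus secretes, lay between 0.66 in male set 1 and -4.44 in male set 3 (± 0.13). HSD17B1, of oestrogen synthesis, lay between 1.39 and -3.36 in the same 2 sets (± 0.12), and HSD11B2, which inactivates cortisol, between 1.88 and -2.83 (± 0.11). Female set 3, also on slide 3, had the second lowest ratio for IL1B (-1.93), IFNG (-2.88), HSD17B1 (-1.61) and HSD11B2 (-2.04). In all, 16503 probes (37.7%) differed between the sets, and 1632 of them had a range over 2 log2 units.

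**Figure D4:**
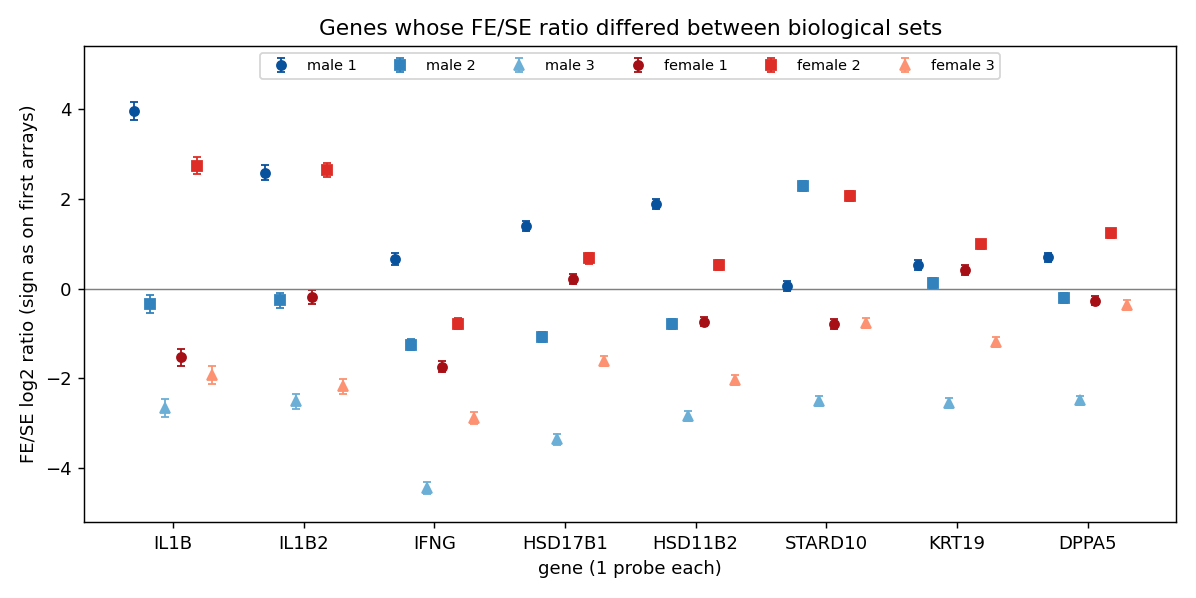
Log2 ratio of FE and SE embryos for 8 genes in each of the 6 biological sets (points, sign as on the first arrays), with the standard error of a set's mean of 2 arrays. The 8 genes were picked for display from those named between sets. Male set 3 had the lowest ratio for all 8 (-2.48 for DPPA5 to -4.44 for IFNG). Female set 3, on the same slide as male set 3, had the second lowest ratio for all of them but STARD10. Other genes of largest F were lowest elsewhere. These were LOC100157017 and KCNE3 in female set 1, STAG2 and PPP4R2 in male set 2, and CAPNS1, PDPN and CALR in female set 3.

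KRT19, a keratin gene of the trophectoderm, had ratios of -2.55 in male set 3 and 0.98 in female set 2, and the tight junction gene CLDN7 of -1.31 and 1.36 in these sets. DPPA5 of pluripotent cells lay at -2.48 in male set 3 and 1.23 in female set 2, and APOE of the hypoblast at -1.73 and 1.71. The uterine marker UPTI, which codes for a protease inhibitor, had -1.47 and 2.14 in these sets, and ACTA2, an actin gene of smooth muscle on the same list, lay between -1.21 in female set 3 and 1.13 in male set 2. The lipid transfer gene STARD10 lay between -2.51 in male set 3 and 2.29 in male set 2, and the cathepsin gene CTSZ between -2.16 in male set 3 and 2.69 in female set 2. In DUSP5, CAPNS1 and PDPN the ratio was highest in female set 2 (1.74, 1.83 and 1.92). CALR, of the endoplasmic reticulum, lay between -2.14 in female set 3 and 1.58 in female set 1, PPP4R2 between -1.74 in male set 2 and 1.95 in female set 1, and the cohesin gene STAG2 between -2.23 and 1.75 in these sets. LOC100157017 and KCNE3 were lowest in female set 1 (-3.37 and -4.04). The other probes of STAG2 and KCNE3 had r of at most 0.315 and 0.198 with these over the 6 sets, and the second probe of PDPN -0.363, so that these patterns rest on 1 probe each.

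Over all named probes, 43.2% differed between sets. The share was 45 of 47 probes for oxidative phosphorylation (Fisher's exact adjusted p = 2.95e-13), 57 of 64 for ribosomal proteins (3.22e-13), 37 of 45 for oxidative stress and heat shock, 32 of 38 for the cell cycle, 21 of 24 for X inactivation and Y-linked genes, 18 of 20 for housekeeping genes and 23 of 30 for trophectoderm markers. In 11 of the 23 lists the share was higher than over all named probes, and in 3 it was lower: blood markers (3 of 24), uterine markers (5 of 27) and gastrulation markers (2 of 15). Fisher's test takes probes as independent, while the 64 ribosomal probes measured 34 genes, so that these p-values are likely too small. No filter on dim probes was run, and whether signal above background set these shares was not analysed. Of the 138 tests of 1 list in 1 set, 28 passed camera's test with the preset correlation and 0 with an estimated correlation. The genes of steroid synthesis and conceptus signalling had a mean of -0.85 in male set 3 and -0.66 in female set 3 (camera adjusted p = 0.000915 and 0.0061, and adjusted p = 0.27 for both with an estimated correlation). Both sets were on slide 3, which held no other set.

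The part of a probe's value that did not follow the turned ratio, the effect of array role, was past limma's threshold for 16848 probes (38.5%), 9701 of them positive and 7147 negative. Its median size over all probes was 0.10 in log2 units. For MAN2C1 it was -0.02 and for B2M 0.22.

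A further group of probes was chosen after its values were seen: those with the same sign in all 6 sets and a mean ratio over 2-fold. NMU, which codes for the peptide neuromedin U, had a ratio of -2.15 ± 1.40 (SD, n = 6 sets), LOC100519082 -1.45 ± 0.86, and B2M and GSTM3 completed the 4 named genes among 68 such probes. The other 64 had no gene symbol, a share of 94.1% against 58.6% of all probes. Of the 68, 60 were positive and 8 negative, 56 kept their sign on all 12 arrays, and 0 passed limma's threshold. Without male set 2 the number was 108, and on first arrays alone 151. Over all probes, 4.14% had 1 sign in all 6 sets, where chance gives 3.12% for independent sets. These sets shared sows, so the excess cannot be told apart from their dependence.

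**Figure D5:**
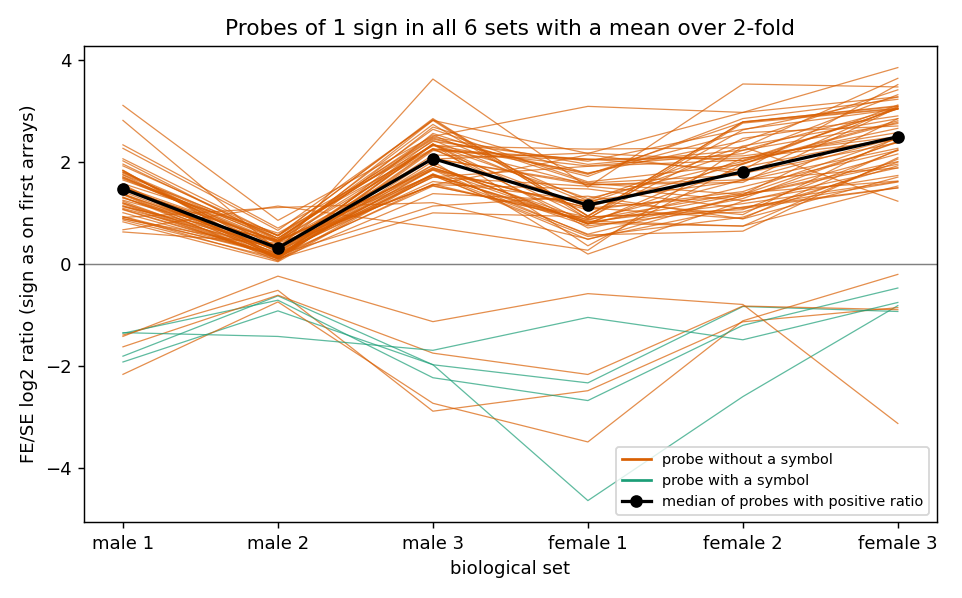
Log2 ratio of FE and SE embryos (vertical axis, sign as on the first arrays) in each of the 6 biological sets for the 68 probes with 1 sign in all sets and a mean over 2-fold, each line joining the values of 1 probe. The median of the 60 positive probes was lowest in male set 2 (0.31) and highest in female set 3 (2.50).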

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

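The tests of the dye effect, of uterine and blood RNA, of slides and of single sets, and the sign patterns for the counts of both, male and female embryos, were chosen after the result was seen.

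A set stood apart from the other 5 in 13 of the 152 gene, list and array values tested. This was judged by its gap to the nearest other set over the whole range of the 6 sets. Chance would give about 7.6 for independent values chosen without these data. Many of the genes were chosen from these data and lists shared members, so setting 13 against 7.6 decides nothing. Male set 3 was the set concerned in 6 of the 13. There COX5B lay at -1.97, with the other sets between 0.06 and 0.66 (gap over range 0.773), ZFP42 at 1.15 (0.713), FDPS at -1.83 (0.681), NQO1 at 0.82 (0.674) and RPL14 at -0.55 (0.643). The mean of the X inactivation and Y-linked genes was 0.47 in that set and between -0.23 and -0.04 in the others (0.724). In male set 1, CDKN1A lay at 0.45 (0.746) and CXCL10 at -0.14 (0.694), and in female set 1 FCER1G at 0.58 (0.767) and NUSAP1 at 1.22 (0.66). In female set 3, YWHAZ lay at -1.51 (0.684) and EIF2AK3 at -0.69 (0.645). The mean of the apoptosis genes was -0.01 in female set 2 and between -0.14 and -0.10 elsewhere (0.709). The differences between sets in COX5B, YWHAZ and FCER1G rested on these gaps, with a limma adjusted p of 0.0881 without male set 3, 0.103 without female set 3 and 0.836 without female set 1.

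The ribosomal protein and oxidative phosphorylation lists differed between male and female embryos in their FE/SE ratio, by -0.36 (camera adjusted p = 8.69e-05) and by -0.28 (0.00069), and both had an adjusted p = 0.932 with an estimated correlation. A difference between slides stays open: on slide 3, which held both sexes, the smaller of the 2 differences was -0.40, but that slide had 1 set per sex, and slides 1 and 2 held 1 sex each. A single set could account for the calls, since without female set 2, 0 of these 2 lists passed, with differences of -0.26 and -0.16, and without male set 3 the differences were smaller still, -0.13 and -0.15, though both lists passed. Of the 10 splits of the 6 sets into 3 and 3, 6 gave 2 or more lists; 10 splits are too few for a share under 0.05, the real split gave 2 lists and the highest other 7, again with male sets 1 and 2 and female set 2 on 1 side. A biological difference between male and female embryos in their response also stays open, and was not tested.

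For the 68 large probes with 1 sign in all 6 sets (64 without a symbol, and NMU, LOC100519082, B2M and GSTM3), 1 of the 32 sign patterns, the real one, gave as many, with 17 in the highest other, but this leaves chance open: the group was chosen for its sign, its positive probes followed nearly 1 profile (median pairwise r 0.889), 0 passed limma's threshold, and without male set 2 there were 108. The test of a dye effect cannot decide. The median array role effect was 0.0716 of the mean ratio of these probes. They were chosen for a mean over 2-fold, from which the role effect cancels, so that a small share was likely from the start. The median size of the role effect was 0.11 in these probes and 0.10 over all probes. For RNA from uterine or blood cells, 0 of the 39 uterine and blood marker genes had a mean ratio over 2-fold, the largest being WFDC2 at -0.38. UPTI and ACTA2 of these lists passed 2-fold in single sets but in both directions (UPTI 2.14 in female set 2 and -1.47 in male set 3, ACTA2 1.13 in male set 2 and -1.21 in female set 3). Whether the other markers were above background was not analysed, so the markers cannot exclude such RNA. What stays open beside these is sequence that FE and SE embryos or their sires carried in different forms, and a true difference in expression, neither of which was tested.

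The 2 probes past the threshold for both sexes, MAN2C1 and probe 1890, were matched by 1 of 32 sign patterns, the real one, and the highest other pattern gave 0. Chance stays open for this count, since the patterns treat the 6 sets as independent while both sexes came from the same 3 sows per group. For the lists, 19 of the 32 patterns gave 2 or more, with 7 in the highest other, which set male sets 1 and 2 and female set 2 against the other 3 sets and points to a structure of the sets, so that chance could account for the cholesterol and oxidative phosphorylation calls. The pattern that set slide 3 against slides 1 and 2 gave 5 lists. With the slide as a fixed block camera's adjusted p was 0.000733 for cholesterol synthesis and 0.0865 for oxidative phosphorylation. With an estimated correlation, and no slide block, camera's adjusted p was 0.815 for both lists. The effect of array role was as large in 1 of 32 patterns, with 16848 probes against 0 in the highest other. For male embryos and for female embryos the 4 patterns are too few for a share under 0.05, and all 4 gave the real count of 0 or more, with 0 in the highest other. For the difference between sexes the 10 splits are too few as well, with a real count of 0, a highest other of 1 and 10 of 10 splits as large.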

How the results depend on the processing

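The lists under centred and scaled arrays and under the slide block, and the large probes, were tested under alternatives chosen after seeing the data, as were the correlation and the precision under the opposite direction.

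MAN2C1 and probe 1890 passed under centring, scaling, robust eBayes, array weights and the slide as a random block. For both sexes limma found 0 probes with the slide as a fixed block (4237 at an unadjusted p under 0.05), 0 with gene means (602), 1 with named probes alone, which tests fewer probes, and 0 to 1 with a set left out. With 1 array per set the dye effect is not cancelled: 155 probes passed on first arrays and 14 on swap arrays, where male and female embryos had 1 each. With 12 separate arrays and the set as a random block the counts were 349, 5 in male and 158 in female embryos (common correlation 0.533); what raised them was not tested. An unadjusted p under 0.05 with 1.5-fold gave 320, 275 in male, 571 in female embryos and 244 for the difference between sexes.

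Under the opposite relative direction the mean returns the dye effect. The counts were then 16335, 8653 in male and 6824 in female embryos, 57 of 107 gene values turned sign, 0 probes differed between sets (135 at an unadjusted p under 0.05), 2 had an effect of array role, the correlation of the sexes was 0.81 and the precision 99.9%.

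Lists passed in both sexes in 0 cases with the estimated correlation and with fry, in 1 with first arrays, in 1 with swap arrays and in 1 to 4 with a set left out. Between sexes the counts were 0, 0, and 1 to 3 with a set left out, and 4 with the slide as a fixed block, which leaves male set 3 against female set 3 alone, since slides 1 and 2 held 1 sex each.

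The sign turned for EED (0.15), HSD17B7 (0.075) and RARA (0.016) on first arrays, and for IGFBP3 (0.12), OGT (-0.13), RPL4 (-0.17), VIM (-0.19), CD3E (-0.024) and, in female embryos, ATP5G3 (-0.32) on swap arrays, which hold the dye effect. With gene means it turned for KDM1A (-0.0026) and NUSAP1 (-0.035), whose other probes differ. None of these had passed over all probes.

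With the set number as a random block across sexes (correlation 0.124) the 2 probes became 0 (smallest adjusted p 0.0643, 2174 at an unadjusted p under 0.05), and with 3 means over the sexes the precision was 95.9%. The main fit did not take the number as a pairing, and the values left this open. Deviations of male and female sets of the same number had r of 0.05, 0.41 and 0.26. Male sets 2 and 3 each correlated best with the female set of their number. Male set 1 had nearly the same r with female set 1 (0.05) and female set 3 (0.06). Male set 3 and female set 3 also lay on the same slide, so their r of 0.26 cannot tell a shared number from a shared slide. Per the labels, male and female pools came from the same sows in each group. The main fit therefore treats sets that share sows as independent, whether or not the numbers pair them.

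The precision was 95.03% to 96.81% with a set left out. The number of large probes was 108 without male set 2 and 151 on first arrays. No filter on dim probes was run, since intensities were not analysed here.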

Other observations

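The test of list members against random lists was chosen before its result was seen, and the tests of lists within 1 sex were chosen after the result was seen.

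Members of some lists varied together over the 6 sets more than random lists of the same size and spread (10000 draws, permutation test). The mean pairwise r was 0.299 for ribosomal proteins (adjusted p = 0.0115), 0.313 for cholesterol synthesis (0.0222), 0.258 for glycolysis (0.0222), 0.281 for X inactivation and Y-linked genes (0.0259), 0.161 for hypoblast markers (0.0402) and 0.193 for oxidative phosphorylation (0.0402). A candidate explanation is that the FE and SE pools of a set differed in how far their embryos had developed. It would need the trophectoderm markers and the conceptus signalling genes to vary together too, and their adjusted p was 0.136 and 0.067, so that the test left it open.

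In female embryos alone camera's test passed for oxidative phosphorylation (mean 0.22, adjusted p = 0.000111), cholesterol synthesis (-0.32, adjusted p = 0.00114) and ribosomal proteins (0.20, adjusted p = 0.00114), each with adjusted p = 0.786 with an estimated correlation. In male embryos 0 lists passed camera's test, with 1 at an unadjusted p under 0.05.

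The 60 positive large probes followed each other closely over the sets, with a median pairwise r of 0.889. Their median ratio was 1.47, 0.31 and 2.07 in male sets 1 to 3 and 1.15, 1.81 and 2.50 in female sets 1 to 3.

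The sets on slide 3 had the widest spread of ratios, with an SD over probes of 0.415 in male set 3 and 0.419 in female set 3, against 0.254 to 0.327 in the other 4 sets.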
